A study of Mus musculus with 16 samples.

How the data were processed

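The study measured messenger RNA of mouse small cell lung cancer cells on 16 Affymetrix arrays. Small cell lung cancer is a neuroendocrine lung tumour, and the cells were 2 lines, 3583T3 and 3151T4, grown from dissociated tumours plated in culture medium. Each line was measured without a vector and with retroviral vectors carrying the complementary DNA of the transcription factor Nfib, of Mycl1 (L-Myc, current symbol Mycl) or both. The Nfib vector held a neomycin resistance gene and the cells were selected with G418, the Mycl1 vector held a puromycin resistance gene and the cells were selected with puromycin, and the Nfib protein carried a FLAG tag, per the labels' protocols. The control cells were untransfected, so the vector and its selection go with the transgene in every comparison with control. By label, Nfib+Mycl1 versus Mycl1 likewise adds the Nfib vector, and Nfib+Mycl1 versus Nfib the Mycl1 vector, each with its resistance gene. Total RNA was taken with Trizol, and 100 ng was amplified with the NuGEN Ovation V2 system and labelled with biotin, per the labels' protocols.

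The deposited table holds 1 log2 signal per probe set and array, made with GCRMA 2.20.0 in R 2.11.0, per the submitters' processing notes. GCRMA corrects the background by probe sequence, normalizes the arrays by quantiles and summarises the probes of a set. That the values are on a log2 scale was taken from their range and from the usual output of that tool, since the labels do not state it. The table has 22690 probe sets. Of these, 64 are control probe sets, 13 of them with a gene symbol, and they were left out of the tests. Of the others, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none; genes were named from the first kind alone. A reference table of current symbols held 20351 of the 20380 by gene number, and 0 symbols differed from it. No column was left out (0).

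Groups and replicate numbers came from the sample titles and sources. Replicates 1 and 2 are line 3583T3 and replicates 3 and 4 line 3151T4, which gives 8 groups of 2 arrays and 4 arrays per vector. Nothing in the labels says that the replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

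For each gene the probe set with the highest mean over the 16 arrays was used, after leaving out probe sets that did not exceed log2 4 on at least 2 arrays, and this left 8777 of 12393 genes. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) over all 16 arrays, with 4 vector levels and cell line as an additive term (11 residual degrees of freedom). The 5 comparisons of vectors, the interaction of Nfib and Mycl1 and the difference between lines came from this model. Responses that differ between lines, and the changes within each line, came from a model with 8 means (8 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the scale of the background-corrected signal, which has a floor near log2 2, and can understate the change of genes at the floor. The number of arrays limits the precision.

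Gene lists were tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, two-sided and adjusted over the lists, and again with the correlation estimated from the data. There were 23 lists with 641 genes: neuroendocrine; neuronal adhesion and axon guidance; epithelial junctions and keratins; mesenchymal transition; extracellular matrix and integrins; Notch pathway; DNA replication and S phase; G2/M and mitosis; cell cycle inhibitors and D cyclins; MYC targets and ribosome biogenesis; MYC and NFI families; glial genes; glycolysis and hypoxia; apoptosis; unfolded protein and integrated stress response; interferon response; cholesterol synthesis; Wnt and hedgehog pathways; chromatin regulators of the Polycomb group; fibroblast markers; endothelial markers; leukocyte markers; lung epithelium markers.

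The lists, the models, the alternatives and the rule for naming genes were chosen before the data were examined. The rule took every probe set of Nfib and Mycl; per comparison of vectors, the 8 genes with the largest rise and the 8 with the largest fall among the called genes whose change had the same sign in both lines (5 and 5 for the interaction, the line difference and the responses that differ between lines); and up to 4 members, those with the smallest p, of each list called by camera or with at least 2 called members, of which 2 per called list are named in the text. Predicted or unnamed clone symbols were skipped.

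Alternatives were no filter on dim probe sets, a stricter one (log2 6), every probe set in place of 1 per gene, a second quantile normalization, centring on array medians, no mean-variance trend, array weights, 8 means, the replicate number as a block, averaged replicates, the control arrays alone for the line difference, a fit of only the 2 vectors compared, a change of at least 2-fold as well, camera with an estimated correlation, the other probe sets of the named genes and leaving out each array in turn. Chosen after seeing the data were leaving out the 2 arrays whose Mycl signal went against their labels, and leaving Mycl and Mycn out of the list of MYC and NFI families.

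Replicate numbers pair arrays of 1 line, which the model holds already as a term. Arrays with the same number did not deviate together throughout: over 12 pairs of groups the correlation of their deviations across genes ran from -0.738 to 0.312 and exceeded 0.1 in 3, and over the 7 pairs without the groups of the 2 arrays in doubt it ran from -0.400 to 0.312. The value with the replicate block is given beside a result only where it changed a call or moved a count by over 1.5 times.

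The procedure was tested on simulated data for Nfib versus control, with 8777 genes, 200 of them changed, in 5 simulations. It recovered 18.5% of genes changed by 0.5 on the log2 scale, 72.8% of those changed by 1 and 96.1% of those changed by 2; 4.15% of its calls were unchanged genes. A list raised by 0.5 was called in 4 of the 5 simulations, and 0 unchanged lists were called. The simulated genes varied independently of each other, so the simulation does not show how often correlated genes give a false list call. In the data the estimated correlation was 0.574 for MYC targets in Nfib versus control.

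The array medians lay between 6.27 and 6.43, and 63.8% to 64.9% of the probe sets exceeded log2 4. Over all probe sets, the 2 arrays of a group correlated at 0.991 to 0.997. The 3′ minus 5′ difference of the actin control probe sets was 0.45 to 0.84 and that of the Gapdh ones 0.24 to 0.82, per array on the log2 scale.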

Results

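Gene expression was measured on 16 arrays in 2 mouse small cell lung cancer lines, 3583T3 and 3151T4. Each line was measured untransfected (control) and after stable expression of Nfib, of Mycl1 or of both, with 2 arrays per line and vector and so 4 per vector. The series asks what Nfib, a transcription factor of the nuclear factor I family, does as an oncogene in this tumour, and the design sets it beside Mycl1, a MYC family oncogene amplified in the disease. Changes below are log2 differences of array signal with their standard error (SE), n = 4 arrays per vector, and levels are mean log2 signals with their SD. Of the 16 arrays, 11 correlated best with the replicate of their own group; the other 5 were the 4 arrays labelled 3583T3 Nfib and 3583T3 Nfib+Mycl1, and replicate 4 of 3151T4 Nfib+Mycl1.

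The Mycl transgene was seen by 1 of the 3 Mycl probe sets, meant below wherever Mycl is named alone. Its signal was 2.34 ± 0.10 (SD, n = 4) in control cells and 10.06 ± 0.73 (SD, n = 4) in cells with the Mycl1 vector, a change of 7.72 ± 1.74 (SE; limma over all probe sets, adjusted p = 0.0204; higher in 4 of 4 arrays). In 2 arrays it went against the label. The array labelled 3583T3 Nfib replicate 2 had 10.22, a level of the arrays with the Mycl1 vector. The other 3 arrays labelled Nfib had 2.32 ± 0.22 (SD, n = 3). The array labelled 3583T3 Nfib+Mycl1 replicate 2 had 2.67, near the control level, and the other 3 of its vector had 10.46 ± 0.54 (SD, n = 3). Both arrays were kept as labelled. The counts of genes and of list members called over both lines are given also without them, an alternative chosen after seeing the data. With all arrays Mycl did not differ in Nfib+Mycl1 versus Nfib (4.22 ± 1.74, adjusted p = 0.106), and without the 2 arrays it rose by 8.14 (adjusted p = 5.4e-09). The other Mycl probe sets did not rise with the Mycl1 vector. Of these, 1 had 6.47 in control cells, 4.76 with Nfib, 5.62 with Mycl1 and 5.15 with both, means that pool different patterns in the 2 lines. In 3151T4 it was at 5.81 to 6.64 on control and Mycl1 arrays and at 3.00 to 3.92 on arrays with the Nfib vector. In 3583T3 it was at 6.48 to 7.30 where the transgene probe set was low and at 4.95 to 5.69 where that was high. The other stayed near the floor (between 2.08 and 2.41 in the 4 means).

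No probe set of Nfib was higher with the Nfib vector. In Nfib versus control the 4 probe sets, with control levels of 10.61, 9.28, 6.73 and 4.52, changed by -0.38 ± 0.13, -0.35 ± 0.16, -0.17 ± 0.31 and -0.08 ± 0.22, with adjusted p from 0.0894 to 0.889. The brightest of them fell in Nfib+Mycl1 versus control (-0.44, adjusted p = 0.0229; lower in 4 of 4 arrays). Whether these probe sets lie within the complementary DNA of the vector was not tested, so the arrays do not check this transgene. Myc, a further member of the family, was lower with Mycl1 than in control (-1.27 ± 0.33, adjusted p = 0.0303).

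**Figure D1:**
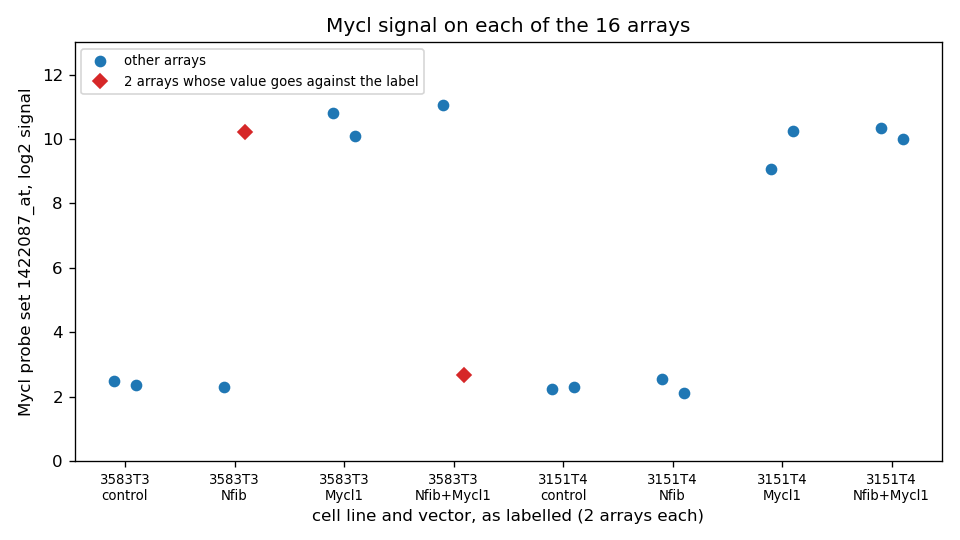
Signal of the Mycl probe set that rises with the Mycl1 vector (log2, vertical axis) on each of the 16 arrays, grouped by line and vector. Red diamonds mark the array labelled 3583T3 Nfib replicate 2 (10.22) and the array labelled 3583T3 Nfib+Mycl1 replicate 2 (2.67). The other arrays with the Mycl1 vector lie between 9.08 and 11.05 and the other arrays without it between 2.12 and 2.55.

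**Figure D2:**
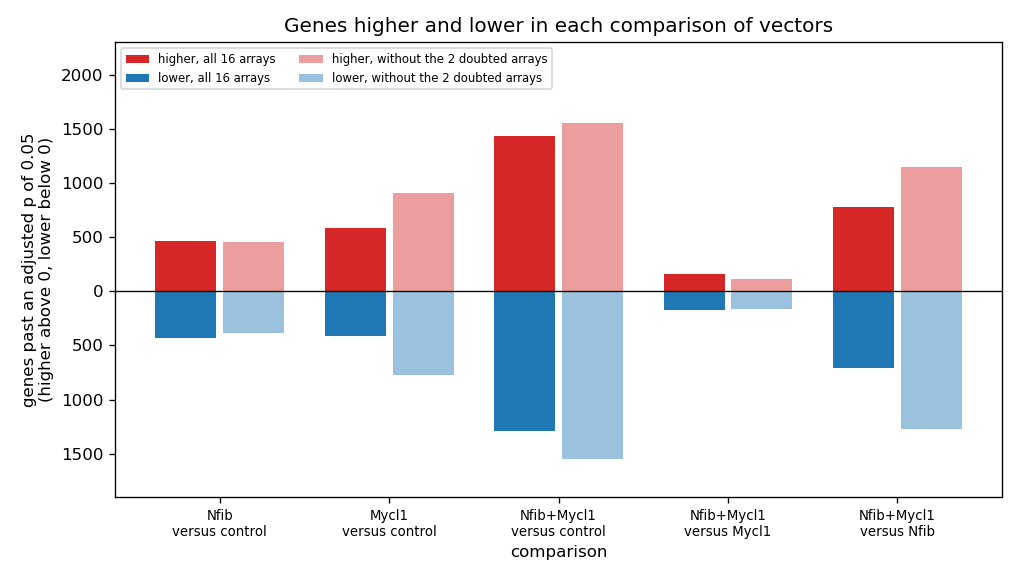
Genes called higher (above 0) and lower (below 0) in each of the 5 comparisons of vectors (number of genes, adjusted p under 0.05), with all 16 arrays (dark bars) and without the 2 arrays whose Mycl signal went against their labels (pale bars). The counts without those arrays are higher for Mycl1 versus control (1685 against 994 genes) and for Nfib+Mycl1 versus Nfib (2420 against 1486). They are lower for Nfib versus control (841 against 900). Mycl1 versus control holds neither array, so only the shared spread of the fit changed there.

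In cells with Nfib, compared with untransfected cells, the largest rises include those of Eln and of interferon-induced genes, and the largest falls were those of macrophage genes. The matrix protein gene Eln (elastin) rose 42.2-fold (5.40 ± 0.62). The carboxylesterase gene Ces2g rose 35.4-fold (5.15 ± 0.76) and Slpi, a secreted protease inhibitor, 30.2-fold (4.92 ± 1.01). Bpifb1, a secreted airway protein, rose by 4.56 ± 0.92, the interferon-induced genes Trim30a and Ifit1 by 4.48 ± 0.70 and 4.32 ± 0.67, and the matricellular protein gene Ccn5 by 4.31 ± 0.88. Some of these means pool unlike lines. In 3583T3 and 3151T4 Slpi rose by 1.77 and 8.06, Bpifb1 by 1.82 and 7.31, Ces2g by 3.34 and 6.96, and Eln by 4.12 and 6.68. The largest rise, 10.19 ± 0.18, was that of Mycn on 1 of its 3 probe sets, which went from 2.38 ± 0.24 to 12.58 ± 0.11 (SD, n = 4). The other 2 Mycn probe sets did not rise (0.01 and -0.05). Genes of macrophages and other leukocytes had the largest falls. These were Lyz1 (-8.50 ± 0.76) and Lyz2 (-7.70 ± 0.43), which encode lysozymes, and C1qb of complement C1q (-8.08 ± 0.37, 272-fold lower). They were followed by the lysosomal protease gene Ctss (-6.10 ± 0.31), Laptm5 (-6.04 ± 0.38), Tyrobp (-5.52 ± 0.41), Clec4d (-5.15 ± 0.68) and Lcp1 (-5.08 ± 0.35). Adjusted p for these 16 genes was at most 0.0057, and each was on its side of the control mean in 4 of 4 arrays.

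In all, 900 genes differed between Nfib and control, 465 higher and 435 lower (841 without the 2 doubted arrays, 457 higher and 384 lower), and 490 of the 900 changed at least 2-fold, 248 higher and 242 lower (493 without those arrays, 269 and 224). With the 2 replicates of each group averaged 18 genes were called, 4 higher and 14 lower. Camera called 5 of the 23 lists, of which 1 held with an estimated correlation. Of 26 interferon response genes tested, 15 rose and 11 did not pass (7 higher without the 2 doubted arrays, and, adjusted over the list alone, 23 higher). Among them were Ifit1 and the class I antigen gene H2-K1 (0.70 ± 0.13, adjusted p = 0.0028; camera adjusted p = 9.3e-13). Of 20 fibroblast markers, 8 rose and 12 did not pass (6 higher without the 2 doubted arrays, and, adjusted over the list alone, 11). They include the collagen VI genes Col6a2 (2.77 ± 0.34) and Col6a1 (1.29 ± 0.19; camera adjusted p = 1.1e-05). Of 20 Wnt and hedgehog genes, 3 rose and 17 did not pass (3 higher without the 2 doubted arrays, and, adjusted over the list alone, 3). Among them were Sfrp2, a secreted Wnt antagonist (1.25 ± 0.11, adjusted p = 5.4e-06), and the hedgehog transcription factor gene Gli2 (1.58 ± 0.41, adjusted p = 0.0228; camera adjusted p = 0.0268). These 3 lists had adjusted p = 0.285 with an estimated correlation. Of 16 genes of epithelial junctions and keratins, 7 fell and 9 did not pass (6 lower without the 2 doubted arrays, and, adjusted over the list alone, 9). Examples are the desmosomal gene Dsp (-2.26 ± 0.35) and the keratin gene Krt19 (-1.52 ± 0.26). This call (camera adjusted p = 6.2e-07) held with an estimated correlation (adjusted p = 0.0029). Of 15 leukocyte markers, 13 fell and 2 did not pass (12 lower without the 2 doubted arrays, and, adjusted over the list alone, 14), with a median of -3.89 (camera adjusted p = 6.2e-27; adjusted p = 0.0625 with an estimated correlation). Without the 2 doubted arrays 8 lists were called. The 3 further ones were MYC targets, then lower (median -0.19, adjusted p = 0.0220), glial genes (0.47, adjusted p = 0.0450) and lung epithelium markers (0.49, adjusted p = 0.0471).

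The Nfib count was 580 without 3583T3 control replicate 1, 577 without 3583T3 control replicate 2, 596 without 3151T4 Nfib replicate 3 and 545 without 3151T4 Nfib replicate 4. Without the array labelled 3583T3 Nfib replicate 2, 8 lists were called. The Wnt and hedgehog call ended without 3583T3 Nfib replicate 1 (median 0.22), 3583T3 control replicate 2 (0.17) or 3151T4 Nfib replicate 4 (0.23). The call of Gli2 ended without any of the 2 control arrays of 3583T3 (1.54 and 1.32), the array labelled 3583T3 Nfib replicate 2 (1.37) or 3151T4 Nfib replicates 3 and 4 (1.49 and 1.58).

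**Figure D3:**
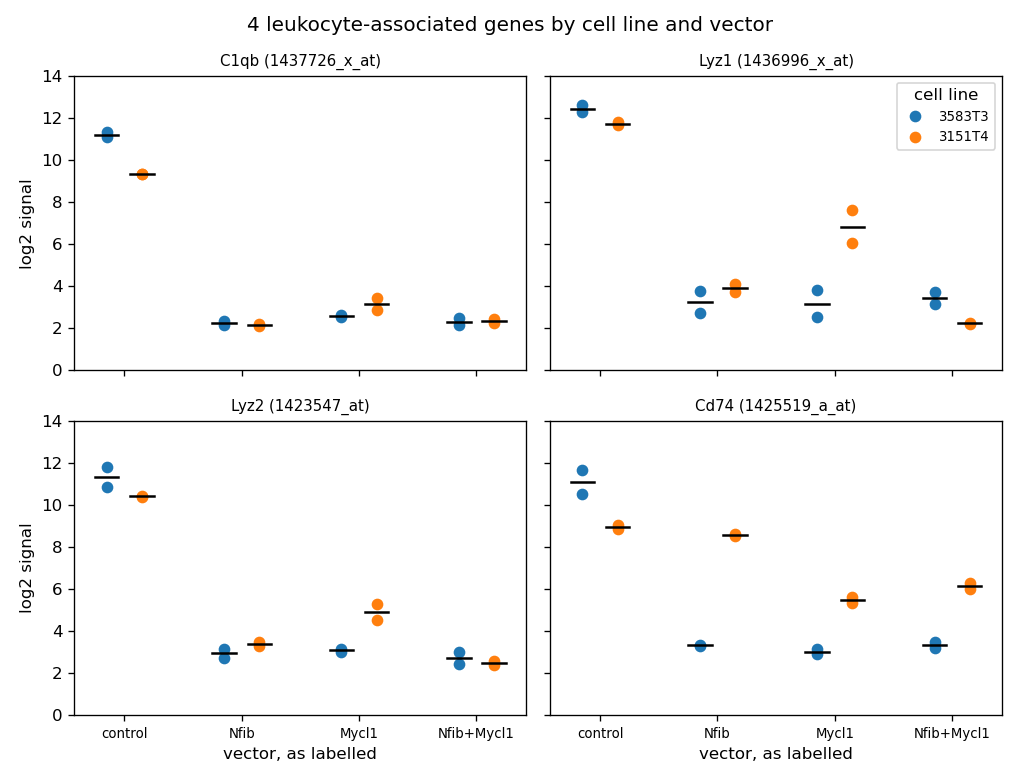
Log2 signal of C1qb, Lyz1, Lyz2 and Cd74 (vertical axes) by line and vector; points are the 2 replicates of each group and black lines their mean. In 3583T3 control cells the means are 11.21, 12.44, 11.31 and 11.08, and Cd74 stays at 8.57 in 3151T4 cells with Nfib while C1qb is at 2.15 there.

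In cells with Mycl1, compared with untransfected cells, the largest rises were those of Mycn and Mycl, on 1 probe set each, and the largest falls those of macrophage genes. Apart from Mycl (7.72 ± 1.75, 210.2-fold, adjusted p = 0.0199) and the same probe set of Mycn (10.35 ± 0.18), the largest rises were those of the nuclear pore gene Nup210 (2.71 ± 0.68, 6.55-fold) and Qtrt1, a subunit of the enzyme that puts queuosine into transfer RNA (1.75 ± 0.34). Next were Ifrd2 (1.68 ± 0.30), Rnf225 (1.61 ± 0.41), the ribosome assembly gene Nle1 (1.55 ± 0.34) and the receptor gene Tnfrsf19 (1.55 ± 0.30). The largest falls were again those of C1qb (-7.42 ± 0.37), Lyz1 (-7.09 ± 0.76) and Lyz2 (-6.87 ± 0.43). Then came Ctss (-5.90 ± 0.31), Cd74, the invariant chain of class II antigen presentation (-5.78 ± 0.98), Laptm5 (-5.74 ± 0.38), Cd53 (-5.21 ± 0.88) and Tyrobp (-4.99 ± 0.41). Adjusted p for these 16 genes was at most 0.0261, and each lay on its side in 4 of 4 arrays. The other probe sets of the top risers did not all follow: another of Mycn changed by -0.71 and another of Mycl by -0.84, neither passing.

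Between Mycl1 and control 994 genes differed, 582 higher and 412 lower, and of the 297 that changed at least 2-fold 100 were higher and 197 lower (376 without the 2 doubted arrays, 111 and 265). The count was 1685 (912 higher, 773 lower) without those arrays, 418 with the replicate block and 5 with averaged replicates. The 2 doubted arrays are of other vectors, so without them the changes here stayed the same and only the shared spread differed. For Mycl, in the fit over all probe sets, the change was 7.72 in both, with an SE of 1.74 and of 0.27 without those arrays. A fit of only the 2 vectors compared gave 1853 genes. Camera called 11 lists, and none held with an estimated correlation, at adjusted p from 0.167 to 0.597. Of 41 MYC targets and ribosome biogenesis genes, 19 rose and 22 did not pass (28 higher without the 2 doubted arrays, and, adjusted over the list alone, 28). Among them were Ppan (1.11 ± 0.20) and Gar1 (0.78 ± 0.17; camera adjusted p = 2.0e-10). Of 32 S phase genes, 6 rose and 26 did not pass (14 higher without the 2 doubted arrays, and, adjusted over the list alone, 11). Members of this group were the helicase subunit gene Mcm5 (0.77 ± 0.14) and the licensing factor gene Cdt1 (0.43 ± 0.11; camera adjusted p = 8.5e-05). Of 34 G2/M genes, the checkpoint kinase gene Bub1b (0.51 ± 0.14) and the condensin gene Ncapd2 (0.52 ± 0.14) rose and 32 did not pass (2 higher without the 2 doubted arrays, and, adjusted over the list alone, 2; camera adjusted p = 0.0313). The median level of the G2/M list was 10.86 in control and 10.83 with Mycl1 in 3583T3, and 10.24 and 10.69 in 3151T4. Of 29 matrix and integrin genes, 4 fell and 25 did not pass (12 lower without the 2 doubted arrays, and, adjusted over the list alone, 13). Among them were the integrin gene Itga9 (-0.96 ± 0.20) and the laminin gene Lama4 (-1.60 ± 0.34; camera adjusted p = 1.2e-09). Of 30 mesenchymal transition genes, 3 fell and 27 did not pass (6 lower without the 2 doubted arrays, and, adjusted over the list alone, 3). Among them were Tgfbr2 (-0.58 ± 0.14) and Tgfb2 (-0.48 ± 0.13), a receptor and a ligand of TGF-beta signalling (camera adjusted p = 0.0046). Of 20 fibroblast markers, 6 fell and 14 did not pass (1 higher and 6 lower without the 2 doubted arrays, and, adjusted over the list alone, 6). Among them were Fstl1 (-0.37 ± 0.06) and Col6a2 (-1.85 ± 0.34; camera adjusted p = 0.0063).

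Of 18 genes of neuronal adhesion, the semaphorin receptor gene Nrp1 fell (-0.45 ± 0.12) and 17 did not pass (3 lower without the 2 doubted arrays, and, adjusted over the list alone, 1), Dpysl3 being at -0.35 with adjusted p = 0.0519 (camera adjusted p = 0.0123). Of 21 apoptosis genes, 1 rose, 3 fell and 17 did not pass (1 higher and 6 lower without the 2 doubted arrays, and, adjusted over the list alone, 1 and 6). Casp12 (-0.78 ± 0.18) and the death receptor gene Fas (-1.16 ± 0.28), which promote cell death, fell (camera adjusted p = 0.0436). Of 29 stress response genes, Atf5 (-0.92 ± 0.17) and Edem1 (-0.64 ± 0.16) fell and 27 did not pass (5 lower without the 2 doubted arrays, and, adjusted over the list alone, 2; camera adjusted p = 0.0146). The interferon list was called lower (camera adjusted p = 0.0075, median -0.34) although 0 of its 26 genes passed in limma, by either adjustment or without the 2 doubted arrays; Irf9 was at -1.11 (adjusted p = 0.0977) and B2m at -0.17 (adjusted p = 0.109). Of 15 leukocyte markers, 13 fell and 2 did not pass (14 lower without the 2 doubted arrays, and, adjusted over the list alone, 14), with a median of -4.19 (camera adjusted p = 1.9e-24; adjusted p = 0.167 with an estimated correlation). None of the 11 list calls held with an estimated correlation: adjusted p = 0.597 for the G2/M and interferon lists, adjusted p = 0.36 for fibroblast markers, and adjusted p = 0.297 for the 7 others besides leukocyte markers. Without the 2 doubted arrays 12 lists were called, the further one being the MYC and NFI families (adjusted p = 0.0317), with Mycl and Mycn as members.

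The Mycl1 count was 391 without 3583T3 control replicate 1, 585 without 3583T3 control replicate 2, and 394 without 3583T3 Mycl1 replicate 1. It was 325 and 172 without 3151T4 control replicates 3 and 4, and 387 and 164 without 3151T4 Mycl1 replicates 3 and 4. Without 1 or more of these 7 arrays 15 of the 33 called genes named above were no longer called: Mycl (7.77 and 7.58 without 3151T4 control and Mycl1 replicate 4), Nup210, Rnf225, Nle1, Nrp1, Tgfbr2, Tgfb2, Lama4, Cdt1, Bub1b, Ncapd2, Gar1, Casp12, Fas and Edem1. With the replicate block 6 lost the call, all at an adjusted p of 0.050 to 0.0547 (Nup210, Tgfb2, Nrp1, Cdt1, Bub1b and Ncapd2). The G2/M call ended without 3151T4 control replicate 3 (median 0.14) or 4 (0.084) or 3151T4 Mycl1 replicate 3 (0.13) or 4 (0.13). The apoptosis call ended without 3583T3 Mycl1 replicate 1 (-0.17) or 2 (-0.13) or 3151T4 control replicate 3 (-0.12), and the stress response call ended without 3583T3 Mycl1 replicate 1 (-0.082).

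In cells with both vectors, compared with untransfected cells, the largest rises beside the same probe set of Mycn (10.73 ± 0.18) and Mycl (6.17 ± 1.75) were those of Slpi (3.48 ± 1.01, 11.1-fold), the retinoic acid binding protein gene Crabp1 (3.20 ± 0.53), the homeobox genes Lhx8 (3.14 ± 1.08) and Prrx1 (3.10 ± 0.53), Gas1, a membrane protein of hedgehog signalling (3.10 ± 0.68), and Eln (3.03 ± 0.62). Lhx8 rose by 0.63 in 3583T3 and 5.66 in 3151T4, Slpi by 1.97 and 4.98, Crabp1 by 4.95 and 1.46, and Gas1 by 4.98 and 1.21. Macrophage genes again had the largest falls: Lyz1 (-9.24 ± 0.76), Lyz2 (-8.27 ± 0.43), C1qb (-7.94 ± 0.37), Laptm5 (-6.20 ± 0.38), Ctss (-5.93 ± 0.31), Cd74 (-5.29 ± 0.98), Tyrobp (-5.27 ± 0.41) and Clec4d (-5.03 ± 0.68). Adjusted p for these 16 genes was at most 0.0389, and each lay on its side in 4 of 4 arrays. For Mycl this held only barely on the array labelled 3583T3 Nfib+Mycl1 replicate 2, at 2.67 against 2.47 and 2.36 in the 3583T3 controls. The rise of Mycl rests on the other arrays of that vector. Of the other probe sets of the named genes, another of Mycn was at -0.57 and another of Mycl at -1.32, neither passing.

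Between Nfib+Mycl1 and control 2721 genes differed, 1432 higher and 1289 lower (3104 without the 2 doubted arrays), and of the 616 that changed at least 2-fold 221 were higher and 395 lower (848 without those arrays, 309 and 539). With averaged replicates 253 were called. Camera called 10 lists, and none held with an estimated correlation, at adjusted p from 0.0864 to 0.702. Of 41 MYC targets and ribosome biogenesis genes, 25 rose, 1 fell and 15 did not pass (31 higher and 0 lower without the 2 doubted arrays, and, adjusted over the list alone, 31 and 1). Among them were Mybbp1a (1.24 ± 0.20) and Gar1 (1.06 ± 0.17; camera adjusted p = 1.0e-07). Of 32 S phase genes, 12 rose, 1 fell and 19 did not pass (16 higher and 0 lower without the 2 doubted arrays, and, adjusted over the list alone, 13 and 1). Among them were Mcm5 (1.25 ± 0.14) and Rfc2 of the clamp loader (1.0 ± 0.14; camera adjusted p = 0.0030). Of 34 G2/M genes, 11 rose and 23 did not pass (10 higher without the 2 doubted arrays, and, adjusted over the list alone, 11). Among them were Ncapd2 (0.81 ± 0.14) and Bub1b (0.74 ± 0.14; camera adjusted p = 0.0040). The median level of the G2/M list was 10.86 in control and 10.81 with both vectors in 3583T3, and 10.24 and 10.77 in 3151T4. That of the S phase list was 10.37 and 10.20 in 3583T3, and 10.43 and 10.95 in 3151T4. Of 29 matrix and integrin genes, 15 fell and 14 did not pass (15 lower without the 2 doubted arrays, and, adjusted over the list alone, 2 higher and 16 lower). They include the basement membrane genes Col4a5 (-1.0 ± 0.16) and Nid1 (-1.35 ± 0.25; camera adjusted p = 0.0012). The median level of the matrix list was 10.36 in control and 10.22 with both vectors in 3583T3, and 10.12 and 8.43 in 3151T4. Of 16 genes of epithelial junctions, 6 fell and 10 did not pass (8 lower without the 2 doubted arrays, and, adjusted over the list alone, 7). Among them were Dsp (-2.19 ± 0.35) and Cdh1, which encodes E-cadherin (-1.0 ± 0.17; camera adjusted p = 0.0030). Of 21 apoptosis genes, 1 rose, 6 fell and 14 did not pass (0 higher and 8 lower without the 2 doubted arrays, and, adjusted over the list alone, 1 and 7). The pro-apoptotic genes Pmaip1 (-2.11 ± 0.28) and Bik (-2.06 ± 0.32) were among those that fell (camera adjusted p = 0.0322).

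Of 20 fibroblast markers, 5 rose, 1 fell and 14 did not pass (4 higher and 1 lower without the 2 doubted arrays, and, adjusted over the list alone, 6 and 1). Among them were Col6a2 (2.05 ± 0.34) and Col6a1 (1.02 ± 0.19, camera adjusted p = 0.0322 for the list). The median level of this list was 9.19 in control and 10.82 with both vectors in 3583T3, and 11.45 and 11.08 in 3151T4. Of 26 interferon genes, Ifit1 (2.15 ± 0.67) and Bst2 (1.49 ± 0.52) rose and 24 did not pass (camera adjusted p = 0.0457). Without the 2 doubted arrays 2 were higher, and adjusted over the list alone 0 passed in limma, against 2 over all genes. Ifit1 rose by 3.96 in 3583T3 and 0.35 in 3151T4, and Bst2 by 2.79 and 0.20. The median level of the list was 4.41 in control and 6.69 with both vectors in 3583T3. In 3151T4 it was 4.88 and 4.57. Of 15 members of the MYC and NFI families, 6 rose, among them Mycn and Mycl, 1 fell and 8 did not pass (5 higher and 1 lower without the 2 doubted arrays, and, adjusted over the list alone, 6 and 1; camera adjusted p = 0.0457). Without Mycl, the transgene, and Mycn, an alternative chosen after seeing the data, 4 of 13 members rose and 1 fell, and the list was not called (median 0.21, camera adjusted p = 0.390). Of 15 leukocyte markers, 14 fell and 1 did not pass (14 lower without the 2 doubted arrays, and, adjusted over the list alone, 15), with a median of -4.22 (camera adjusted p = 6.5e-17; adjusted p = 0.228 with an estimated correlation). None of the 10 calls held with an estimated correlation: adjusted p = 0.0864 for epithelial junctions, adjusted p = 0.492 for the MYC and NFI families, adjusted p = 0.702 for interferon, and adjusted p = 0.528 for the 6 others besides leukocyte markers. With the replicate block the MYC and NFI and the interferon calls ended (adjusted p = 0.0535 each), and without the 2 doubted arrays the interferon call (median 0.39, adjusted p = 0.171) and the fibroblast call (0.49, adjusted p = 0.101).

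The count was 1807 without 3151T4 Nfib+Mycl1 replicate 3. Mycl was no longer called without 3583T3 Nfib+Mycl1 replicate 1 (5.32), or without replicate 3 (5.44) or 4 (5.56) of 3151T4 Nfib+Mycl1. Slpi was lost without 3151T4 control replicate 3 (3.12) or 4 (3.05) or Nfib+Mycl1 replicate 3 (3.31), and Lhx8 was lost without any of the 4 arrays of 3151T4 control (2.63 and 2.58) and Nfib+Mycl1 (2.75 and 2.79). Lhx8 was also lost with the block (adjusted p = 0.0640), as was Bst2 (adjusted p = 0.0672). Without the 2 doubted arrays Ifit1 and Bst2 were lost (adjusted p = 0.0618 and 0.0610). The interferon and the fibroblast calls each ended without 3583T3 control replicate 1 (medians 0.42 and 0.51) or 2 (0.52 and 0.62) or the arrays labelled 3583T3 Nfib+Mycl1 replicate 1 (0.27 and 0.53) and 2 (0.40 and 0.49). These 4 arrays also ended the calls of Ifit1 (1.95, 2.02, 1.46 and 1.88) and Bst2 (1.26, 1.43, 0.93 and 1.43), the latter lost also without 3151T4 control replicate 3 (1.64) or 4 (1.66). The MYC and NFI call ended without 3583T3 Nfib+Mycl1 replicate 1 (0.31), 3583T3 control replicate 2 (0.22), 3151T4 control replicate 3 (0.28) or 4 (0.30) or 3151T4 Nfib+Mycl1 replicate 3 (0.24), and the apoptosis call ended without the last (-0.17).

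The comparison of Nfib+Mycl1 with Mycl1 is by label that of the Nfib vector with none in cells with the Mycl1 vector, but the array labelled 3583T3 Nfib+Mycl1 replicate 2 had a Mycl signal of only 2.67. The extracellular superoxide dismutase gene Sod3 rose 16.7-fold (4.06 ± 0.81), Col6a2 14.9-fold (3.90 ± 0.34) and Trim30a by 3.85 ± 0.70. They were followed in order by Crabp1 (3.78 ± 0.53), the proteoglycan genes Prelp (3.31 ± 0.60) and Dcn (3.27 ± 0.73), the VEGF receptor gene Flt1 (3.27 ± 0.29) and Eln (3.02 ± 0.62). The largest falls were those of Bex1 (-3.38 ± 0.46, 10.4-fold), the neural receptor phosphatase gene Ptprz1 (-2.68 ± 0.31), Car8 (-2.64 ± 0.49), Padi2 (-2.37 ± 0.27). Next were the pro-apoptotic gene Bik (-2.35 ± 0.32), a probe set of Trav9d-3 (-2.35 ± 0.17), Cytip (-2.33 ± 0.52) and Chodl (-2.28 ± 0.23). Adjusted p for these 16 genes was at most 0.0240, and each lay on its side in 4 of 4 arrays.

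Between Nfib+Mycl1 and Mycl1 331 genes differed, 156 higher and 175 lower, and of the 141 that changed at least 2-fold 83 were higher and 58 lower (147 without the 2 doubted arrays, 65 and 82). The count was 285 without those arrays, 138 with the replicate block and 0 in limma with averaged replicates (1125 at an unadjusted p under 0.05). Of 16 genes of epithelial junctions, 3 fell and 13 did not pass (4 lower without the 2 doubted arrays, and, adjusted over the list alone, 5). Examples are the desmosomal genes Pkp2 (-0.71 ± 0.15) and Dsp (-1.63 ± 0.35). Their call (camera adjusted p = 9.5e-05) held with an estimated correlation (adjusted p = 0.0152). Of 20 fibroblast markers, 5 rose and 15 did not pass (3 higher without the 2 doubted arrays, and, adjusted over the list alone, 8). Among them were Col6a2 and Col6a1 (2.00 ± 0.19; camera adjusted p = 3.9e-09; adjusted p = 0.156 with an estimated correlation). Of 26 interferon genes, 3 rose and 23 did not pass (1 higher without the 2 doubted arrays, and, adjusted over the list alone, 9). Among them were H2-D1 (0.83 ± 0.18) and Ifi35 (1.10 ± 0.26; camera adjusted p = 3.9e-09; adjusted p = 0.573 with an estimated correlation). Of 25 genes of glycolysis and hypoxia, 3 rose and 22 did not pass (3 higher without the 2 doubted arrays, and, adjusted over the list alone, 6). Members of this group were the hypoxia-induced genes Bnip3 (0.67 ± 0.10) and Ndrg1 (0.72 ± 0.14; camera adjusted p = 0.0282; adjusted p = 0.152 with an estimated correlation). Of 15 leukocyte markers 0 passed in limma, by either adjustment or without the 2 doubted arrays (median -0.23, camera adjusted p = 0.397). Without the 2 doubted arrays 6 lists were called, the further ones being G2/M (median 0.15, adjusted p = 0.0173) and MYC targets (0.13, adjusted p = 0.0175).

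The count was 535 without 3583T3 Mycl1 replicate 1, 138 without 3583T3 Mycl1 replicate 2 and 105 without 3583T3 Nfib+Mycl1 replicate 1. It was 170 without the array labelled 3583T3 Nfib+Mycl1 replicate 2, 114 without 3151T4 Mycl1 replicate 3 and 180 without 3151T4 Nfib+Mycl1 replicate 3. Of the 23 called genes named, Sod3, Dcn, Eln, Cytip, Pkp2, Dsp, H2-D1 and Ifi35 were lost without 1 or more of these arrays. Each of the 8 was lost without 3151T4 Mycl1 replicate 3 (3.82, 3.05, 2.96, -2.24, -0.70, -1.59, 0.84 and 1.13), and Dcn also without 3151T4 Mycl1 replicate 4 (3.01). Dcn, Cytip and Ifi35 were lost with the block (adjusted p = 0.0532, 0.0551 and 0.0675), and Cytip and Ifi35 without the 2 doubted arrays (adjusted p = 0.0616 and 0.0706). The glycolysis call ended without 3583T3 Mycl1 replicate 1 (median 0.24), 3583T3 Nfib+Mycl1 replicate 1 (0.18) or 3151T4 Mycl1 replicate 4 (0.24).

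The comparison of Nfib+Mycl1 with Nfib is by label that of the Mycl1 vector with none in cells with the Nfib vector. Each side holds 1 array whose Mycl signal went against this, 2.67 on the array labelled 3583T3 Nfib+Mycl1 replicate 2 and 10.22 on the array labelled 3583T3 Nfib replicate 2. Nup210 rose 5.35-fold (2.42 ± 0.68) and the nucleolar genes Nop14, Pum3 and Nolc1 by 1.40 ± 0.26, 1.34 ± 0.27 and 1.34 ± 0.27. Next were the phosphatase gene Dusp9 (1.31 ± 0.42), Rcc2 (1.30 ± 0.31), Pprc1 (1.30 ± 0.19) and the kinase gene Dyrk3 (1.29 ± 0.39). The complement protease gene C1s1 (-2.59 ± 0.49), the angiotensin receptor gene Agtr2 (-2.58 ± 0.83), Ces2g (-2.55 ± 0.76) had the largest falls. They were followed by the matrix metalloproteinase gene Mmp3 (-2.51 ± 0.82), the interferon-induced gene Iigp1 (-2.44 ± 0.56), the chemokine gene Cxcl5 (-2.41 ± 0.68), Vegfd (-2.38 ± 0.61) and Eln (-2.37 ± 0.62). Adjusted p for these 16 genes was at most 0.0467. Nup210, Mmp3, Cxcl5 and Eln lay on their side in 3 of 4 arrays and the other named genes in 4 of 4. The change in 3583T3 rests on both doubted arrays, and without them on 1 array per side. Eln changed there by -0.18 (0.47 without them) and by -4.57 in 3151T4, Mmp3 by -0.33 (-2.26) and -4.69, Cxcl5 by -0.15 (-0.54) and -4.67, and Nup210 by 0.46 (2.12) and 4.38. Agtr2 changed by -0.15 (0.30) and -5.00, Ces2g by -0.91 (1.26) and -4.18, and Iigp1 by -0.76 (0.59) and -4.11. For these 3 genes and Eln the fall in 3583T3 was not seen without the doubted arrays. C1s1 (-0.89, or -1.48 without them) and Vegfd (-0.66, or -0.26) stayed lower in 3583T3.

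Between Nfib+Mycl1 and Nfib 1486 genes differed, 780 higher and 706 lower, and of the 206 that changed at least 2-fold 67 were higher and 139 lower (700 without the 2 doubted arrays, 248 and 452). With 8 means 1127 genes were higher and 1352 lower. The count was 2420 (1148 higher, 1272 lower) without those arrays, 945 with the replicate block and 0 in limma with averaged replicates (1738 at an unadjusted p under 0.05). Camera called 7 lists, and all were lost with an estimated correlation (adjusted p = 0.586 for each). Of 41 MYC targets and ribosome biogenesis genes, 25 rose, 1 fell and 15 did not pass (30 higher and 0 lower without the 2 doubted arrays, and, adjusted over the list alone, 28 and 1). Among them were Mybbp1a (1.28 ± 0.20) and the nucleolar methyltransferase gene Fbl (1.23 ± 0.19; camera adjusted p = 7.4e-11). Of 34 G2/M genes, 7 rose and 27 did not pass (5 higher without the 2 doubted arrays, and, adjusted over the list alone, 10). Among them were the mitotic kinesin gene Kif20a (0.90 ± 0.18) and Ncapd2 (0.69 ± 0.14; camera adjusted p = 0.00046). Of 32 S phase genes, 8 rose, 1 fell and 23 did not pass (13 higher and 0 lower without the 2 doubted arrays, and, adjusted over the list alone, 9 and 3). Among them were Fen1 (0.80 ± 0.15) and Mcm5 (0.74 ± 0.14; camera adjusted p = 0.0288). The median level of the G2/M list was 10.79 with Nfib and 10.81 with both vectors in 3583T3, and 10.36 and 10.77 in 3151T4. That of the S phase list was 10.54 and 10.20 in 3583T3, and 10.60 and 10.95 in 3151T4. Of 26 interferon genes, 7 fell and 19 did not pass (8 lower without the 2 doubted arrays, and, adjusted over the list alone, 10). Among them were H2-K1 (-0.60 ± 0.13) and Irf9, a transcription factor of the interferon response (-1.97 ± 0.43, camera adjusted p = 3.5e-05 for the list). Without the 2 doubted arrays H2-K1 changed by -0.08 and Irf9 by 0.11 in 3583T3, against -0.83 and -3.27 in 3151T4. Of 29 matrix and integrin genes, 4 fell and 25 did not pass (12 lower without the 2 doubted arrays, and, adjusted over the list alone, 2). Among them were Col4a5 (-0.94 ± 0.16) and Lamb1 (-0.89 ± 0.22; camera adjusted p = 0.0128), and the median was -0.34 with all arrays and -0.59 without the 2 doubted arrays. The median level of the matrix list was 10.27 with Nfib and 10.22 with both vectors in 3583T3, and 9.97 and 8.43 in 3151T4. Of 21 apoptosis genes, 4 fell and 17 did not pass (7 lower without the 2 doubted arrays, and, adjusted over the list alone, 4). Among them were Casp12 (-1.02 ± 0.18) and Xiap (-0.62 ± 0.13), which inhibits caspases (camera adjusted p = 0.0489). Of 20 Wnt and hedgehog genes, Fzd7 (-0.96 ± 0.19) and Tcf7l2 (-0.56 ± 0.17) fell and 18 did not pass (5 lower without the 2 doubted arrays, and, adjusted over the list alone, 2; camera adjusted p = 0.0489). Of 15 leukocyte markers 0 passed in limma, by either adjustment or without the 2 doubted arrays (median -0.09, camera adjusted p = 0.882). Without the 2 doubted arrays 8 lists were called, the further one being glial genes (median -0.71, adjusted p = 0.0173).

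This comparison rested on single arrays more than the others. It called 0 genes in limma without 3151T4 Nfib replicate 4 (2206 at an unadjusted p under 0.05) and 1 without 3151T4 Nfib+Mycl1 replicate 3. Each of the 30 called genes named lost its call without 3151T4 Nfib replicate 4, at adjusted p of 0.0566 or more. The count was 683 without 3151T4 Nfib replicate 3, 728 without 3151T4 Nfib+Mycl1 replicate 4 and 975 without 3583T3 Nfib+Mycl1 replicate 1, and 3 lists were called without 3151T4 Nfib replicate 3 or without 3151T4 Nfib+Mycl1 replicate 4. Some calls also ended without 3583T3 Nfib replicate 1 (Dyrk3 1.25, Mmp3 -2.77 and Tcf7l2 -0.52) or the array labelled 3583T3 Nfib+Mycl1 replicate 2 (Ces2g -2.30). With the block Dusp9, Dyrk3, Agtr2, Ces2g, Mmp3 and Tcf7l2 were lost (adjusted p from 0.0562 to 0.0780), and without the 2 doubted arrays Ces2g (adjusted p = 0.0673). Among the lists, the matrix call ended without 3151T4 Nfib replicate 3 (median -0.34) or Nfib+Mycl1 replicate 4 (-0.28). The S phase, apoptosis and Wnt calls each ended without 3151T4 Nfib replicate 3 (0.17, -0.13 and -0.21), Nfib+Mycl1 replicate 3 (0.13, -0.096 and -0.19) or Nfib+Mycl1 replicate 4 (0.13, -0.11 and -0.24). The S phase and Wnt calls ended also without 3151T4 Nfib replicate 4 (0.14 and -0.30), and the S phase and apoptosis calls without 3583T3 Nfib+Mycl1 replicate 1 (0.18 and -0.18). Further, the apoptosis and Wnt calls without 3583T3 Nfib replicate 1 (-0.24 and -0.38), and the apoptosis call with the block (adjusted p = 0.0508).

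Genes for which the change with both vectors differed from the sum of the single changes numbered 27, 25 positive and 2 negative, all of at least 2-fold (18 without the 2 doubted arrays, 13 positive and 5 negative; 149 with 8 means, 88 positive and 61 negative; 13 with the replicate block and 1 with averaged replicates). For 23 of the 25 positive ones the sum of the single changes would put the signal with both vectors below 0.475, the lowest signal of the table, so the floor sets their interaction and it is no measure of a departure from that sum. The largest were those of C1qb (7.56 ± 0.52), Lyz1 (6.35 ± 1.08), Lyz2 (6.30 ± 0.60), Ctss (6.07 ± 0.44) and Laptm5 (5.58 ± 0.54), all among the 23. For Pld4, not among the 23, that sum gives 0.674, also under the floor near log2 2. The negative ones were the same probe set of Mycn (-9.81 ± 0.26), high with each vector alone, and Frat1, a Wnt pathway gene (-1.27 ± 0.25, adjusted p = 0.0431). For Mycn the sum gives 22.9, against 12.58 with Nfib, 12.73 with Mycl1 and 13.12 with both. Whether the signal can reach such a level was not tested. Without the 2 doubted arrays Lyz1 and Frat1 were not called (adjusted p = 0.0697 for both). The count was 13 without 3583T3 control replicate 1, 12 and 14 without 3583T3 Mycl1 replicates 1 and 2, and 15 without the array labelled 3583T3 Nfib replicate 2. It was 16 without 3151T4 Mycl1 replicate 3, and 16 and 15 without 3151T4 Nfib+Mycl1 replicates 3 and 4.

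Between the 2 lines, with 8 arrays each, 5141 genes differed, 2429 higher in 3583T3 and 2712 higher in 3151T4 (5085 without the 2 doubted arrays, and 3512 in the control arrays alone). Higher in 3583T3 were the Y-linked gene Eif2s3y (8.85 ± 0.12), the matrix protein gene Efemp1 (7.86 ± 0.22), Ctla2a (7.44 ± 0.27), the tight junction gene Cldn6 (6.99 ± 0.32) and Mal2 (6.68 ± 0.27). Higher in 3151T4 were Igfbp5, which binds insulin-like growth factors (-8.18 ± 0.22), Islr (-7.77 ± 0.23), the neuroendocrine enzyme gene Ddc (-7.76 ± 0.34), the homeobox gene Rhox5 (-7.53 ± 0.20) and Xist, the RNA of X inactivation (-7.40 ± 0.17). Adjusted p for these 10 genes was at most 9.1e-11, with 8 arrays per line.

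For Nfib 601 genes had a response that differed between lines, 241 more positive in 3583T3 and 360 more negative (668 without the 2 doubted arrays). More positive in 3583T3 were Cd34 (4.8, against -1.54 in 3151T4), the homeobox gene Hoxa10 (5.19 against -0.98), the matrix protein gene Postn (6.59 against 0.51) and Ptx3 (6.30 against 0.26). The smooth muscle actin gene Actg2 was at 0.87 there and at -4.65 in 3151T4. More positive in 3151T4 were the hypoxia-induced carbonic anhydrase gene Car9 (8.13 against -0.28 in 3583T3), the proteoglycan gene Epyc (7.07 against 0.12), Ecrg4 (7.40 against 0.56) and Lhx8 (7.26 against 0.53), and Cd74 was at -0.38 there against -7.77. For Mycl1 187 genes differed (380 without the 2 doubted arrays, 122 with the replicate block). Rgs5 (1.05 in 3583T3, -4.44 in 3151T4), Ccn5 (2.39, -2.81), Sod3 (0.22, -4.33), Gas1 (2.92, -1.16) and Lbp (-0.04, -3.78) were more positive in 3583T3. The myeloid genes Ccl6 (-6.02, -0.68), Arg1 (-6.20, -1.51), Cd74 (-8.07, -3.49), Lyz1 (-9.28, -4.89) and Clec4d (-6.85, -2.70) were more negative there. For both vectors 524 genes differed (767 without the 2 doubted arrays). More positive in 3583T3 were Postn (6.33, -0.67), Cd34 (4.45, -2.32), the Wnt antagonist genes Sfrp1 (4.33, -2.35) and Dkk2 (1.49, -4.84) and F13a1 (0.05, -6.26). More negative there were Bex4 (-5.50, 1.34), Ugt2b34 (-6.10, 0.30), Car9 (-0.42, 5.69) and the muscle genes Tnnc2 (0.06, 5.76) and Myh11 (-5.20, -0.11). Some of these differences are set by the floor: the change of the line with the greater fall would take the other line below log2 3, and the level seen there lay under log2 4. This test, chosen after seeing the data, held for 119 of the 601 genes for Nfib, 83 of the 187 for Mycl1 and 149 of the 524 for both vectors. Of the genes named it held for Rgs5, Sod3, Lbp, Ccl6, Arg1 and Clec4d with Mycl1 and for F13a1, Bex4, Ugt2b34 and Myh11 with both vectors, for which the arrays cannot show a fall as large in the other line. Within single lines Nfib versus control had 886 genes in 3583T3 and 1208 in 3151T4 (634 and 1626 without the 2 doubted arrays), and Mycl1 versus control 258 and 1426 (1058 and 2073). Nfib+Mycl1 versus Nfib had 0 in 3583T3 (limma; 1361 at an unadjusted p under 0.05, and 425 adjusted calls without the 2 doubted arrays) and 2608 in 3151T4 (3077). Without those arrays 3583T3 has 1 array with Nfib and 1 with both vectors, so the spread behind the 425 calls comes from the other groups alone.

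These 3 counts also moved with single arrays. The count for Nfib was 358 without 3583T3 control replicate 2, 380 and 361 without 3151T4 control replicates 3 and 4, and 360 and 343 without 3151T4 Nfib replicates 3 and 4. The count for Mycl1 was 115 and 91 without 3583T3 control replicates 1 and 2, 91 without 3583T3 Mycl1 replicate 1, 100 and 74 without 3151T4 control replicates 3 and 4, and 78 and 84 without 3151T4 Mycl1 replicates 3 and 4. The count for both vectors was 344 without 3583T3 control replicate 2, 341 without 3151T4 control replicate 4 and 321 without 3151T4 Nfib+Mycl1 replicate 3.

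The remaining lists were called in none of the 5 comparisons with all arrays. Of the 28 neuroendocrine genes 24 were on the array, and only 8 were bright enough to be tested. Camera adjusted p ran from 0.177 to 0.990 for this list and from 0.278 to 0.598 for Notch. It ran from 0.122 to 0.761 for cell cycle inhibitors and D cyclins, from 0.0609 to 0.510 for glial genes, from 0.128 to 0.772 for cholesterol synthesis. It ran from 0.108 to 0.882 for the Polycomb group, from 0.177 to 0.882 for endothelial markers and from 0.128 to 0.481 for lung epithelium markers. The median level of the neuroendocrine list lay near the floor in each of the 8 groups, between 2.56 and 2.93. That of the mesenchymal transition list lay between 11.03 and 11.58. Several lists had called members in both directions without a call of the list. In Nfib versus control 4 genes of neuronal adhesion rose and 2 fell, 3 mesenchymal genes rose and 4 fell, and 4 genes of glycolysis and hypoxia rose and 1 fell (5 and 2 without the 2 doubted arrays, the others alike). In Nfib+Mycl1 versus control 3 stress response genes rose and 8 fell (3 and 7 without those arrays), 3 mesenchymal genes rose and 6 fell (3 and 7), and 5 glycolysis and hypoxia genes rose and 3 fell (6 and 3). In Mycl1 versus control 5 members of the MYC and NFI families, Mycl and Mycn among them, rose and 1 fell, with and without those arrays (camera adjusted p = 0.0658; 3 rose and 1 fell without these 2 genes, camera adjusted p = 0.700). The median, the mean and the camera direction differed in sign, in lists not called there, for G2/M, MYC targets, apoptosis and stress response in Nfib versus control and for neuroendocrine, epithelial, MYC and NFI and cholesterol genes in Mycl1 versus control. So they did for Wnt and hedgehog genes in Nfib+Mycl1 versus control, for matrix, S phase, glial and endothelial genes in Nfib+Mycl1 versus Mycl1 and for mesenchymal and endothelial genes in Nfib+Mycl1 versus Nfib.

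Each effect, that of a transgene together with its vector, was estimated in pairs of comparisons that share no array. Across genes, which are not independent replicates, the change in Nfib versus control correlated with that in Nfib+Mycl1 versus Mycl1 at r = 0.659. In these 2 comparisons 103 genes were called higher in both (8.26 by chance for independent lists) and 80 lower in both (8.67 by chance). For Mycl1, the change against control correlated with that in Nfib+Mycl1 versus Nfib at r = 0.539 (0.641 without the 2 doubted arrays), with 244 genes higher in both (51.7 by chance) and 122 lower in both (33.1 by chance). Between lines, r was 0.437 for Nfib, 0.587 for Mycl1 and 0.50 for both vectors. Nfib versus control and Mycl1 versus control use the same 4 control arrays. Their changes correlated at r = 0.375, against 0.50 in 100 simulations of unchanged groups set against those controls, and their covariance was 0.137 against a simulated 0.0332, a difference of 0.104. With the controls split between the comparisons r was 0.320 and 0.352. Of their calls 49 were higher in both (30.8 by chance for independent lists) and 110 lower in both (20.4 by chance). The shared controls make these lists dependent, so the chance counts cannot decide whether the overlap exceeds chance.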

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

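The tests of mixed RNA, of macrophage RNA, of repression by the vectors and of the Mycn probe set were chosen only after the results they test were seen, as was leaving out the 2 arrays in doubt.

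In 28 groups of 4 arrays, 1 per vector and probe set of the target genes, 3 signals, on 2 arrays, lay far from the other 3 of their group by Dixon's test, which by chance marks about 1 group in 20. The array labelled 3583T3 Nfib replicate 2 had a Mycl signal of 10.22, far above the other Nfib arrays. The array labelled 3583T3 Nfib+Mycl1 replicate 2 had 2.67, far below the others of its vector. That array also had the highest signal of its vector on the brightest Nfib probe set (10.34).

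An exchange of these 2 arrays is a candidate explanation, tested on the genes other than Mycl: the difference of the first from its replicate 1 should follow the difference between Nfib+Mycl1 and Nfib in 3151T4, and that of the second the reverse. The correlations over 8776 genes were 0.211, narrowly past the 0.2 set before the test, and -0.270, against 0.043, -0.129, -0.114 and 0.131 in the 4 other groups. Each array also correlated best with replicate 1 of the other label (0.995 for both, against 0.991 and 0.992 with its own), and a second Mycl probe set crossed likewise in 3583T3 (Nfib 7.28 and 4.95, Nfib+Mycl1 5.60 and 7.30, replicates 1 and 2), which no planned test covers. Mixing in of RNA without the Mycl1 vector is argued against for the second array, whose Mycl lay only 0.114 above the highest of 7 other arrays without the vector, and for the first array mixing was not excluded, since its Mycl lay 1.14 above the lowest of 7 other arrays with the vector, inside their range. No biological explanation was tested, and the labels were kept.

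The median level of the leukocyte list was 6.04 in untransfected 3583T3 cells and 3.90 in untransfected 3151T4 cells, against 2.32 to 2.72 with the vectors in both lines. A general loss of dim signals is argued against: 719 genes matched to these by their control level changed by at most 0.0658 in the median over the 3 comparisons with control, against -3.89 to -4.22 for the leukocyte list. RNA of macrophages left in the untransfected cultures, and lost under selection, could give the pattern. A separate list of 32 macrophage genes, 22 of them tested, fell by over 1 in the median in 6 of 6 combinations of line and vector, from -2.75 (Nfib+Mycl1 in 3583T3) to -1.05 (Nfib+Mycl1 in 3151T4). This test cannot decide, since a gene dim with the vectors passes the filter only by exceeding log2 4 in controls. The same holds for the 15 leukocyte genes tested. The combinations of a line also share its 2 control arrays. With Nfib 13 of the 15 leukocyte genes and 19 of the 22 were called lower and 0 higher. Some genes stayed up, among them Cyba (10.31 in control and 9.92 with Nfib) and, in 3151T4 alone, Cd74 (8.95 and 8.57). In 3583T3 Cd74 went from 11.08 to 3.31 with Nfib. In 3151T4 it was at 5.46 with Mycl1 and at 6.15 with both vectors. These few genes leave open whether macrophage RNA was the whole source. On the arrays with 1 vector, 6 of the 15 leukocyte genes and 8 of the 22 of the separate list had a mean of at least log2 3. Such a signal can lie under the log2 4 taken as dim. It does not tell expression in the tumour cells from remaining macrophage RNA. Repression by Nfib and Mycl1 in the tumour cells cannot be told apart from a loss of macrophage RNA, since the leukocyte list differed by only 0.297 between the 2 vectors with 60% of its genes near the floor, and vector and selection go together.

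The Mycn probe set with a rise of over 10 on the log2 scale in every comparison with control was the only 1 of 22626 probe sets on which every array with a vector lay above every control array by over 1, and its gap was 9.63. Higher expression of the whole Mycn transcript is argued against, since the highest change of the other Mycn probe sets with the single vectors was 0.0136 and the lowest -0.71. A sequence common to both vectors that the probe set detects is a possible explanation, since the level with Mycl1 lay only 0.156 above that with Nfib; the vector sequences were not at hand to search. No biological explanation was tested further.

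Of the genes named in the comparisons of vectors, 49 of 144 changed by a different amount in the 2 lines, by a test of the difference (given as 3583T3 minus 3151T4). For 11 of the 49 the floor sets the difference, by a test chosen after seeing the data: C1qb, Tyrobp and Clec4d with Nfib, C1qb and Tyrobp with Mycl1, C1qb, Ctss, Tyrobp and Clec4d with both vectors, and Agtr2 and Iigp1 in Nfib+Mycl1 versus Nfib. Without the 2 arrays in doubt, which leaves 1 array each for Nfib and Nfib+Mycl1 in 3583T3, each of the 49 still differed, and so did 1 more gene in Nfib versus control, 1 in Mycl1 versus control and 5 in Nfib+Mycl1 versus Mycl1. With all arrays they were, in Nfib versus control, 8 of 23: Eln (-2.56), Ces2g (-3.62), Slpi (-6.29), Bpifb1 (-5.49), C1qb (-1.77), Tyrobp (-2.04), Clec4d (-3.72) and Dsp (2.06). In Mycl1 versus control they were 7 of 36: C1qb (-2.44), Lyz1 (-4.39), Lyz2 (-2.74), Cd74 (-4.58), Cd53 (-2.59), Tyrobp (-2.64) and Col6a2 (2.25). In Nfib+Mycl1 versus control they were 15 of 32. Among these were Slpi (-3.01), Crabp1 (3.49), Lhx8 (-5.03), Gas1 (3.77), Eln (1.83), C1qb (-1.91), Ctss (-1.58) and Cd74 (-4.97). The rest were Tyrobp (-2.07), Clec4d (-4.28), Dsp (2.25), Nid1 (1.76), Ifit1 (3.60), Bst2 (2.58) and Col6a2 (1.81). In Nfib+Mycl1 versus Mycl1 they were 4 of 23: Trim30a (4.27), Prelp (1.75), Dsp (1.25) and Ndrg1 (0.83). In Nfib+Mycl1 versus Nfib they were 15 of 30, given first with all arrays and then without the 2 arrays in doubt. Among these were Nup210 (-3.91, -2.26), Pum3 (-1.57, -1.42), Nolc1 (-1.64, -1.27), Dusp9 (-2.13, -1.92) and Rcc2 (-1.88, -1.71). Further ones were C1s1 (3.41, 2.82), Agtr2 (4.85, 5.30), Ces2g (3.27, 5.45), Mmp3 (4.36, 2.43) and Iigp1 (3.35, 4.70). The rest were Cxcl5 (4.52, 4.14), Vegfd (3.45, 3.85), Eln (4.39, 5.03), Lamb1 (1.34, 1.16) and Irf9 (2.61, 3.38).

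The genes chosen for a response that differed between lines had these differences. The floor sets 6 of the 10 for Mycl1 (Rgs5, Sod3, Lbp, Ccl6, Arg1 and Clec4d) and 4 of the 10 for both vectors (F13a1, Bex4, Ugt2b34 and Myh11). For Nfib they were Cd34 (6.35), Hoxa10 (6.17), Postn (6.07), Ptx3 (6.05), Actg2 (5.52), Car9 (-8.41), Cd74 (-7.39), Epyc (-6.94), Ecrg4 (-6.85) and Lhx8 (-6.73). For Mycl1 they were Rgs5 (5.49), Ccn5 (5.20), Sod3 (4.55), Gas1 (4.08), Lbp (3.74), Ccl6 (-5.34), Arg1 (-4.69), Cd74 (-4.58), Lyz1 (-4.39) and Clec4d (-4.15). For both vectors they were Postn (7.0), Cd34 (6.77), Sfrp1 (6.68), Dkk2 (6.33), F13a1 (6.31), Bex4 (-6.84), Ugt2b34 (-6.40), Car9 (-6.12), Tnnc2 (-5.71) and Myh11 (-5.09).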

How the results depend on the processing

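Leaving out the 2 arrays in doubt, and Mycl and Mycn from their list, was chosen after seeing the data; the other alternatives were planned. A second quantile normalization and centring on array medians left every count within 1.5 times of its value, as did the fit without a mean-variance trend, and the correlations between comparisons moved by under 0.1. Signals near the floor limit what the arrays can show. The cause was not tested for any change below, except that fewer arrays or averaged replicates leave fewer residual degrees of freedom. Also, Mycl1 versus control holds neither array in doubt, so leaving these out alters only the shared spread there, not the changes.

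Counts moved by over 1.5 times as follows. Without a filter the interaction had 44 genes, and with a stricter one 14, with 106 for the line-dependent Mycl1 response. With every probe set, where more features are counted, Mycl1 versus control had 1574, Nfib+Mycl1 versus control 4574, Nfib+Mycl1 versus Nfib 2424 and the lines 9176. With array weights Nfib and Mycl1 versus control had 2163 and 2082, and Nfib+Mycl1 versus Mycl1 and Nfib 662 and 4015. With 8 means these 4 had 1553, 2053, 1076 and 2479, and the interaction 149 (88 positive and 61 negative). With the replicate block Mycl1 versus control had 418, Nfib+Mycl1 versus Mycl1 138 and versus Nfib 945, the interaction 13 and the line-dependent Mycl1 response 122. With averaged replicates the comparisons with control had 18, 5 and 253, the interaction 1, and Nfib+Mycl1 versus Mycl1 and Nfib 0 each in limma (1125 and 1738 at an unadjusted p under 0.05). With a 2-fold minimum the 5 comparisons had 490, 297, 616, 141 and 206. With only the 2 vectors fitted Mycl1 versus control had 1853. Without the 2 arrays in doubt it had 1685, Nfib+Mycl1 versus Nfib 2420, the line-dependent Mycl1 response 380, and Nfib versus control 8 lists. With an estimated correlation the lists called by limma's camera were 1, 0, 0, 1 and 0 (for the zeros, 3, 2 and 0 at an unadjusted p under 0.05).

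Lists that lost their call kept their direction (medians). Without a filter these were Wnt and hedgehog in Nfib versus control (0.077), neuronal adhesion (-0.058) and apoptosis (-0.041) in Mycl1 versus control, MYC and NFI in Nfib+Mycl1 versus control (0.21) and Wnt in Nfib+Mycl1 versus Nfib (-0.12). With a stricter filter they were MYC and NFI (0.27) and interferon (0.37) in Nfib+Mycl1 versus control and Wnt in Nfib+Mycl1 versus Nfib (-0.40). With quantile normalization they were interferon (0.51) and fibroblast (0.63) in Nfib+Mycl1 versus control, glycolysis in Nfib+Mycl1 versus Mycl1 (0.21) and apoptosis in Nfib+Mycl1 versus Nfib (-0.13). The block ended MYC and NFI (0.27) and interferon (0.52) in Nfib+Mycl1 versus control and apoptosis (-0.14) in Nfib+Mycl1 versus Nfib, and changed no other list call. Without the 2 arrays in doubt interferon (0.39) and fibroblast (0.49) were lost in Nfib+Mycl1 versus control, as was MYC and NFI (0.21) without Mycl and Mycn.

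Leaving out 1 array at a time, a lone array of a group being assumed to vary like the others, gave 545 to 1065 genes for Nfib versus control, 164 to 1168 for Mycl1, 1807 to 2883 for both, 105 to 535 for both versus Mycl1, 0 to 2058 for both versus Nfib (limma; 2206 at an unadjusted p under 0.05 where 0) and 12 to 40 for the interaction. Responses that differ between lines ran from 343 to 901, 74 to 134 and 321 to 549. Lists called ran from 4 to 8 for Nfib versus control, 3 to 6 for both versus Mycl1 and 3 to 8 for both versus Nfib. Medians of lists ran from 0.17 to 0.32 (Wnt, Nfib), 0.084 to 0.22 (G2/M, Mycl1), -0.17 to -0.071 (apoptosis, Mycl1), -0.19 to -0.082 (stress response, Mycl1), 0.22 to 0.34 (MYC and NFI, both), -0.28 to -0.17 (apoptosis, both), 0.27 to 0.69 (interferon, both) and 0.49 to 0.73 (fibroblast, both). They ran from 0.18 to 0.29 for glycolysis in both versus Mycl1, and in both versus Nfib from -0.51 to -0.21 (matrix), 0.13 to 0.27 (S phase), -0.31 to -0.096 (apoptosis) and -0.43 to -0.19 (Wnt).

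Of the tests of other probe sets of named genes, 170 kept side and direction, 86 no longer passed, 8 newly passed and 18 turned direction. The last were another Mycn (-0.71 with Mycl1, -0.57 with both), Mycl (-0.84, -1.32), Bcl2l2 (0.037) with Mycl1, and Maml1 (0.21), Nfib (0.17) and Col5a2 (-0.47) with both. In Nfib+Mycl1 versus Nfib they were Efnb2 (0.073), Cd44 (0.084), Cdh2 (0.0054), Slc2a1 (0.026 and 0.35), Hsp90b1 (0.016), H2-K1 (0.00052), Fzd2 (0.21 and 0.29) and Kdm6a (0.21). Of the genes chosen by the rule, called or not, the block left 300 on the same side of the threshold and ended 53 calls. Leaving out the 2 arrays in doubt left 321 on the same side, ended 19 calls and added 13. None of these changed direction.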

Other observations

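The tests on other splits were planned, and those of the interaction and line used 100 drawn splits; the part of the splits balanced within each line was chosen after the results were seen.

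Each count was tested by splitting the same arrays otherwise, with line as a covariate in a fit of the 8 arrays compared. For Nfib versus control, 1 of 34 splits, the real one, gave as many genes (877, against at most 6 in the others). The same held for Mycl1 versus control (1 of 34; 1853 against at most 2), Nfib+Mycl1 versus control (1 of 34; 2884 against at most 7) and Nfib+Mycl1 versus Mycl1 (1 of 34; 326 against 0, limma). For Nfib+Mycl1 versus Nfib 2 of 34 splits gave as many, the real one with 1268 and another with 1318, and that other split is the one that exchanges the 2 arrays whose Mycl signal went against their labels. Only 18 of the 34 splits exchange arrays within a line alone, which are too few for a share under 0.05; of these, 1 gave as many genes in each of the first 4 comparisons and 2 in the last. The other splits also hold the vector difference in their residual spread, which lowers their counts.

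For the interaction, 5 of 100 permutations of the vectors within lines gave as many genes as the real 27, with up to 817. Such a permutation carries the differences between vectors into the interaction, so these counts reflect the vectors as a structure of the samples, and the test does not decide whether chance gives the real count. For the lines, 1 of 100 splits, the real one, gave 5141 genes, against at most 644. The other splits hold the line difference in their residual spread, which lowers their counts, so this test does not decide about chance.

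Counts of lists were not beyond other splits. As many lists were called in 12 of 34 splits for Nfib versus control (real 5, highest other 7), in 14 of 34 for Mycl1 versus control (8 and 11), in 11 of 34 for Nfib+Mycl1 versus control (8 and 11), in 24 of 34 for Nfib+Mycl1 versus Mycl1 (3 and 9) and in 7 of 34 for Nfib+Mycl1 versus Nfib (8 and 10). Chance cannot be excluded for the number of lists called.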
